A study of Caenorhabditis elegans with 8 samples.

How the data were processed

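The authors deposited 1 table per experiment, 4 in all, each with 46748 features and columns for every library. Per the file headers, the deposited columns hold exon read counts in total and unique form, intron read counts, RPKM (reads scaled by exon length and library size) and the p-values of a test of PD against CON. Total exon read counts, as deposited by the authors, were the values tested here. The RPKM values deposited by the authors were used only to check the counts, and 99.98% matched a value recomputed from count, exon length and library total within a relative tolerance of 1e-06. The p-values of the authors' deposited tables were used only for the comparison with the calls made here. Per the submitters' processing notes the test was run with edgeR, and no version was named. The aligner, its settings, the genome build, the annotation release and whether counting used the strand are not given in the sources used here. Raw reads were not analysed here.

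Strain and inducer were taken from the deposited table that held a column. History was read from the second letter of a code in the column name, where C was taken to mean CON and P to mean PD. All columns of a library could be matched in this way. The 24962 features with an exon length of 0 were left out, which left 21786 to be filtered. Symbols and gene types were looked up in the WBcel235 annotation, in which 64.47% of the features found there had the same start and end after a shift of 1 base. A gene was called uncertain where the share of its exon reads that were unique was low or another annotated feature overlapped its span on either strand.

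Counts were filtered with filterByExpr, scaled by TMM and fitted with the edgeR quasi-likelihood model with robust dispersion shrinkage, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. The threshold was an adjusted p under 0.05. Each experiment was fitted alone, with 1 residual degree of freedom in N2 pheromone, where the lone CON library was assumed to vary like the PD libraries, and 2 in each other experiment. The 10 comparisons were the 4 experiments, their shared change (counts summed per group, experiment as a factor, 3 residual degrees of freedom), the inducer difference in each strain, the strain difference for each inducer, and WM193 against N2 in CON adults, the last 5 in a fit of all 8 groups with 7 residual degrees of freedom. Inducer differences are starvation minus pheromone, and strain differences are WM193 minus N2. Gene lists, 31 in number, were fixed before the data were examined, as were the comparisons, the naming rule and the alternatives other than those said to have been added. Lists were tested with camera, with its preset correlation of 0.01 and with an estimated one, and with fry. List counts are given over all genes tested and adjusted over the list alone. Overlaps were tested with Fisher's exact test among genes tested in both experiments.

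Genes were named by this rule. In each comparison the 5 highest and 5 lowest genes past the threshold with a mean of at least 5 CPM were taken, and in an experiment all PD libraries had to lie on one side of all CON libraries. Up to 2 changed members per direction of each list followed, with a mean of at least 1 CPM. Genes without a symbol were counted and the next gene with one was named, and csr-1 was always given. The rule set a limit of 30 genes per comparison. The further genes named under other observations took N2 starvation past that limit.

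Alternatives tried were DESeq2 size factors, upper-quartile and total-count scaling, the DESeq2 Wald test, the edgeR exact test, limma-voom, other filters, removal of genes with near-identical copies, an 8-group fit, stricter thresholds, a block for the library number, and leaving out each library. The library number of that block is the order of a library within its group, by the numbers in the column names. Unique exon reads, lane terms, a fit of the 7 CON libraries alone, leaving out a library or adding a block in the 8-group fit of N2 pheromone, and leaving out the first WM193 starvation CON library from the shared-change fit were added after seeing the data.

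A self-test drew negative binomial counts with the means, dispersions and library sizes of these data and changed 200 genes in each comparison, 50 at each of log2 1, 2, 3 and 4 in size. The changed genes had a mean of at least 5 CPM, so recovery at lower levels was not tested. In N2 starvation 8, 80, 98 and 100% were recovered with 3 false calls. In N2 pheromone 40, 94, 100 and 98% were recovered, but 37 unchanged genes were also called, 18.2% of all calls, which exceeds the nominal 5%. In WM193 pheromone 4, 64, 84 and 90% were recovered with 13 false calls, and in WM193 starvation 0, 44, 68 and 92% with 2. For the inducer difference in N2 recovery was 0, 16, 48 and 82%, and for the strain comparison in CON adults 18, 70, 98 and 100%. For the inducer difference in WM193 it was 0, 16, 64 and 76%. For the strain difference it was 2, 6, 44 and 78% with pheromone and 0, 16, 56 and 88% with starvation.

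The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.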

Results

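Polyadenylated RNA was measured by sequencing in whole adults of the nematode Caenorhabditis elegans. The animals belonged to 2 strains, the wild type N2 and WM193. WM193 carries the tm892 allele of csr-1, which encodes an Argonaute protein of the germline small RNA pathways, together with a transgene that expresses tagged csr-1 from the pie-1 promoter and the marker unc-119. Adults had either developed continuously (CON) or passed through the dauer larva, a stress-resistant resting stage, before resuming growth (post-dauer, PD). Dauer had been induced by crowding pheromone or by starvation, and each inducer had its own CON adults. These factors gave 8 groups and 15 libraries, with 2 libraries in 7 groups and 1 library in N2 pheromone CON. Each PD against CON comparison within a strain and an inducer is called an experiment.

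The total exon read count was 8424878 in the lone N2 pheromone CON library, and 18955815 and 15534469 in N2 pheromone PD. It was 21474286 and 27615452 in N2 starvation CON, and 17916111 and 33895845 in N2 starvation PD. In WM193 it was 34207760 and 39517015 in pheromone CON, 34218819 and 34805591 in pheromone PD, 36734370 and 30029561 in starvation CON, and 32221458 and 39290296 in starvation PD. The yolk gene vit-6 took the largest share of exon reads in every library, from 1.031% to 6.019%. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. The 4 lanes named in the column headers were not spread evenly over the groups: lane 5 held the N2 pheromone CON library alone and lane 6 both N2 pheromone PD libraries, whereas each N2 starvation group and each WM193 pheromone group had 1 library in either of 2 lanes. Fold changes are log2 of PD over CON with the standard error (SE), and levels are read counts scaled to a common library size by the trimmed mean of M-values (TMM) and written as CPM. A gene is said to have risen or fallen only where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05.

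Starvation-induced dauer passage in N2 was compared with continuous development to ask what trace that history leaves in the adult. Oocyte and DNA replication genes were lower in PD adults, and genes of defence, cuticle, detoxification and neuropeptides were higher. The eggshell gene cbd-1 measured 2476 and 5265 CPM in the 2 CON libraries and 1032 and 463 CPM in the 2 PD libraries (log2 -2.42 ± 0.53 SE). The oocyte regulator lin-41 fell by 2.44 ± 0.60, the P-granule gene meg-1 by 2.26 ± 0.45, the replication helicase gene mcm-3 by 2.02 ± 0.45 and the ribonucleotide reductase gene rnr-1 by 1.99 ± 0.46. Histone methyltransferase genes fell as well, mes-4 by 1.79 ± 0.48 and set-2 by 1.74 ± 0.51, as did the germline Argonaute gene wago-1 by 1.72 ± 0.44. Within the insulin receptor pathway, the lipid phosphatase gene daf-18 fell by 1.63 ± 0.42 and the kinase gene age-1 by 1.47 ± 0.42, whereas the kinase genes sgk-1 and akt-2 rose by 1.36 ± 0.32 and 1.24 ± 0.36. The insulin-like peptide gene ins-19 measured 5.52 and 0.686 CPM in CON and 100.7 and 113.4 CPM in PD (log2 5.11 ± 0.70), and ins-7 rose by 3.62 ± 0.64. The largest rises with a symbol and at least 5 CPM also included dct-3 (5.54 ± 0.54), far-3 (5.34 ± 1.13), the cytochrome P450 gene cyp-13A5 (5.15 ± 0.61) and the fatty acid desaturase gene fat-5 (4.67 ± 0.65). Of these, far-3 measured 25.49 CPM in the first PD library and 592.8 in the second, against 10.61 and 4.848 in CON. The desaturase gene fat-7 rose by 2.18 ± 0.43, the lysozyme gene lys-3 by 5.67 ± 0.73, the lectin gene clec-5 by 3.37 ± 0.44, the metallothionein gene mtl-1 by 3.83 ± 0.53, dod-3 by 3.27 ± 0.38, the neuropeptide gene nlp-39 by 6.16 ± 0.81 and the troponin C gene pat-10 by 1.497 ± 0.395. Each gene named here had both PD libraries on the same side of both CON libraries, and its adjusted p lay between 0.00281 and 0.0315 (edgeR quasi-likelihood, Benjamini-Hochberg). Values of far-3, fat-5, mcm-3 and age-1 are uncertain because another annotated feature overlaps each, and those of puf-3 (-2.86) and his-48 (-2.85), the lowest with a symbol above 5 CPM, because 10.9% and 8.3% of their exon reads were unique.

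Of 14224 genes tested in N2 starvation, 2363 rose and 2009 fell. All 26 DNA replication and cell cycle genes had a lower value, with 25 falling over all genes tested and 26 adjusted over the list alone (median log2 -1.48). Among oocyte and eggshell genes 21 of 23 fell, and 21 adjusted over the list alone (median -1.75), and among germline and meiosis genes 27 of 36 fell, and 33 adjusted over the list alone (median -1.197). Chromatin modifiers fell in 18 of 31 cases, 25 adjusted over the list alone (median -1.12). In the opposite direction, 41 of 56 antimicrobial and immune genes rose, 45 adjusted over the list alone (median 1.66), and 59 of 128 cuticle collagens rose, 70 adjusted over the list alone (median 1.43, or 0.92 without the second PD library). Neuropeptide genes rose in 38 of 67 cases, 45 adjusted over the list alone (median 1.499), detoxification enzymes in 70 of 147, 78 adjusted over the list alone (median 1.28), and intestine genes in 17 of 26, 18 adjusted over the list alone (median 1.25). Fry, which asks whether a list moves on balance one way, called 0 lists (smallest adjusted p = 0.129, fry, Benjamini-Hochberg). Its mixed test, for changes in either direction, called 0 as well. None of the medians of the lists named here changed sign under another scaling of the counts. The camera test with a preset correlation called these lists, and with an estimated correlation none passed (oocyte genes, adjusted p = 8.78e-12 with the preset value and adjusted p = 0.6 with an estimated correlation; edgeR-filtered counts, Benjamini-Hochberg). The call count was 0 without the second CON library, with 3072 genes at an unadjusted p under 0.05, and 1275 without the second PD library. Upper-quartile scaling moved the median of all genes from 0.055 to 0.468 (library totals, to 0.189) and changed the split to 2720 higher and 408 lower.

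The N2 pheromone comparison asked the same question for dauer induced by crowding, with 1 CON library against 2 PD libraries. Here germline, small RNA and chromatin genes were higher in PD adults, while cuticle collagens and antimicrobial genes were lower. In each of these groups the lone CON library also stood apart from the N2 starvation CON libraries, which lay near PD. The oocyte regulator lin-41 measured 163.6 CPM in CON and 441.6 and 680.2 CPM in PD (log2 1.74 ± 0.34 SE). The poly(A) polymerase gene gld-2 rose by 1.57 ± 0.22, the cyclin E gene cye-1 by 1.47 ± 0.22, the replication licensing gene cdt-1 by 1.23 ± 0.18 and meg-1 by 1.31 ± 0.25. Among small RNA genes, the double-stranded RNA channel gene sid-1 rose by 1.41 ± 0.20 and the nucleotidyltransferase gene cid-1 by 1.25 ± 0.16. The methyltransferase genes set-2 and met-1 rose by 1.46 ± 0.21 and 1.40 ± 0.26, the insulin receptor gene daf-2 by 1.42 ± 0.21, and the homeobox gene ceh-100 by 1.74 ± 0.29. The small heat shock gene hsp-16.41 fell by 3.73 ± 0.21, from 57.8 CPM in CON to 4.346 and 4.644 CPM in PD, but the other CON libraries of both strains had 1.235 to 6.291 CPM, so only the lone CON library stood apart. In N2, the lone CON library likewise lay outside the range of the pheromone PD and starvation CON libraries for every gene named in this paragraph, with rps-9 at 5050 CPM against 1629 and 1721 CPM in starvation CON, and pat-10 at 1295 against 452 and 283.9. The saposin-like gene spp-2 fell by 3.12 ± 0.49, the collagen gene col-121 by 3.09 ± 0.48, the cathepsin-like protease gene cpr-1 by 1.93 ± 0.22, pat-10 by 1.64 ± 0.18 and the desaturase gene fat-2 by 1.17 ± 0.17. The neuropeptide genes nlp-40 and nlp-29 fell by 1.73 ± 0.16 and 1.71 ± 0.33, and the ribosomal protein genes rpl-11.2 and rps-9 by 1.47 ± 0.29 and 1.45 ± 0.23. Both PD libraries lay on the same side of the CON library for each gene named here, and adjusted p lay between 0.0306 and 0.0393, except 0.0408 for rpl-11.2 (edgeR quasi-likelihood, Benjamini-Hochberg). The highest gene with a symbol and a mean of at least 5 CPM, dpl-1 (1.82 ± 0.18), is uncertain because 40.2% of its exon reads were unique, as is hsp-16.48 (-2.96) with 0.4%.

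Of 13534 genes tested in N2 pheromone, 1538 rose and 771 fell. Small RNA pathway genes rose in 25 of 48 cases, 35 adjusted over the list alone (median log2 0.88), and germline and meiosis genes in 12 of 36, 19 adjusted over the list alone (median 0.57). Insulin receptor pathway genes rose in 10 of 17 cases, 14 adjusted over the list alone (median 0.97), and chromatin modifiers in 15 of 31, 17 adjusted over the list alone (median 0.76). Cuticle collagens fell in 34 of 132 cases, 38 adjusted over the list alone (median -1.13, or -1.80 and -0.75 without the first and the second PD library), antimicrobial and immune genes in 22 of 56, 28 adjusted over the list alone (median -1.38), and ribosomal proteins in 14 of 78, 17 adjusted over the list alone (median -0.40). Each of these differences was also seen between the lone CON library and N2 starvation CON, where PD was close to the latter. Ribosomal proteins took 15.45% of exon reads in the lone library, 8.581% and 9.072% in starvation CON and 10.96% and 9.762% in PD. Small RNA genes took 0.4893% in the lone library, 0.7159% and 0.7898% in starvation CON and 0.7745% and 0.8321% in PD. In a comparison added after seeing the data, the median log2 ratio of pheromone PD to N2 starvation CON was -0.088 for small RNA, 0.107 for germline, -0.21 for insulin receptor pathway, -0.017 for chromatin, 0.052 for collagen, -0.072 for antimicrobial and 0.083 for ribosomal protein genes. An unusual CON library was therefore not told apart from an effect of dauer history. By fry 0 lists passed, whether for a move on balance one way or for changes in either direction. The medians of the lists named here kept their sign under each scaling tried. The camera test called these lists with a preset correlation but none with an estimated one (antimicrobial genes, adjusted p = 2.95e-14 with the preset value and adjusted p = 0.737 with an estimated correlation; Benjamini-Hochberg). The lone CON library was assumed to vary like the PD libraries, and an edgeR quasi-likelihood fit of all 8 groups, which pools the spread, called 0 genes and left 2141 at an unadjusted p under 0.05, against 2438 calls by the DESeq2 Wald test. CON and PD libraries shared no lane, and upper-quartile scaling moved the median of all genes from -0.063 to -0.306 and turned the split into 571 higher and 870 lower.

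**Figure D1:**
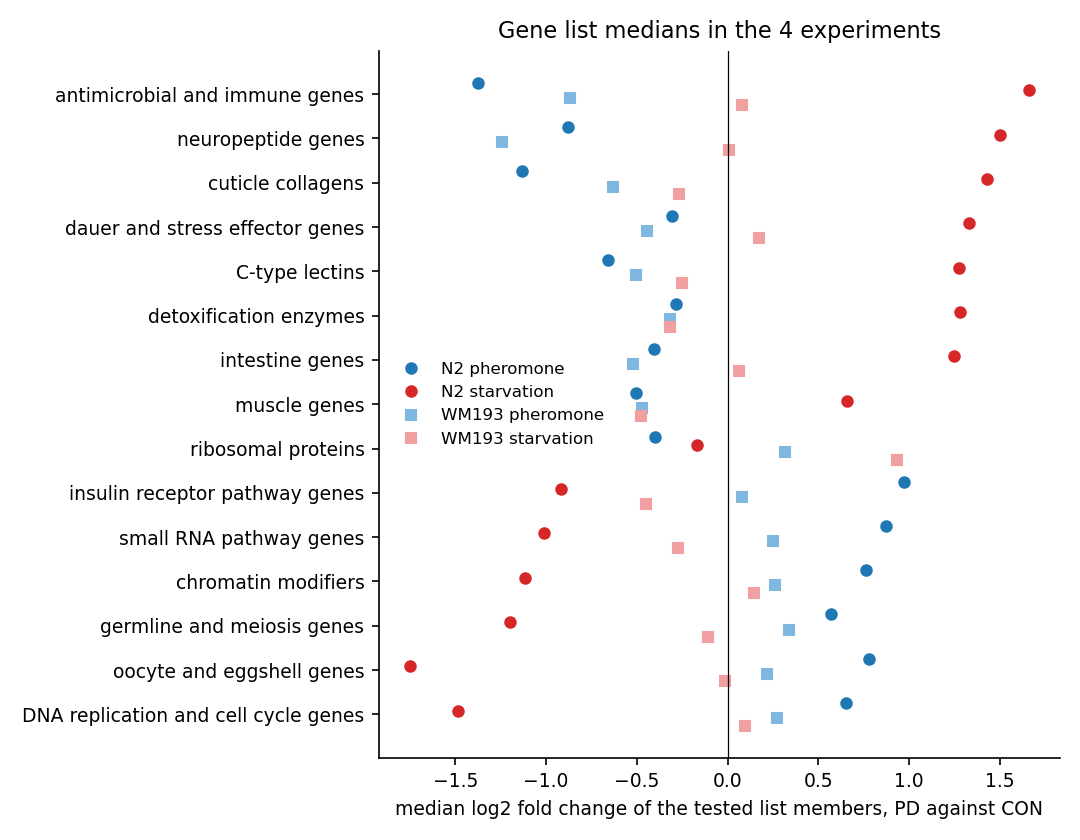
Median log2 fold change (PD over CON, x axis) of the tested members of 15 gene lists in N2 (circles: blue pheromone, red starvation) and WM193 (squares: light blue pheromone, pink starvation). Oocyte and eggshell genes lie at -1.75 in N2 starvation and small RNA pathway genes at 0.88 in N2 pheromone, while upper-quartile scaling flips the sign of ribosomal proteins in N2 starvation (-0.17 to 0.29; 0.04 with library totals), of insulin receptor pathway genes in WM193 pheromone (0.08 to -0.02) and of neuropeptide genes in WM193 starvation (0.007 to -0.026).

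The difference between the N2 experiments was tested as an interaction, starvation effect minus pheromone effect, to ask whether the inducer matters for the adult transcriptome. Germline and replication genes had a lower starvation effect, and defence, stress and intestine genes a higher one. The ins-19 difference was 9.43 ± 1.62 SE, with 30.22 CPM in pheromone CON and a mean of 1.439 CPM in pheromone PD, which was not called in that experiment, and means of 3.102 and 107.1 CPM in starvation CON and PD. Differences were also positive for spp-2 (5.78 ± 0.87), mtl-1 (5.76 ± 0.99), hsp-16.41 (5.51 ± 0.97, with the lone pheromone CON library at 57.8 CPM above all others), fat-5 (4.86 ± 1.05), cpr-1 (3.11 ± 0.69), rpl-11.2 (3.13 ± 0.55), pat-10 (3.01 ± 0.49) and fat-2 (2.84 ± 0.50). They were negative for lin-41 (-4.25 ± 0.96), meg-2 (-3.86 ± 0.71), meg-1 (-3.66 ± 0.74), cbd-1 (-3.58 ± 0.88), cye-1 (-3.44 ± 0.72), set-2 (-3.28 ± 0.84), met-1 (-3.16 ± 0.76), the translational repressor gene gld-1 (-3.097 ± 0.883), rnr-1 (-3.07 ± 0.69), the Argonaute gene ergo-1 (-2.70 ± 0.64) and daf-18 (-2.68 ± 0.60). Adjusted p lay between 0.015 and 0.0308 for these genes (edgeR quasi-likelihood, Benjamini-Hochberg). Values of gla-3 (-3.98), puf-3 (-3.86), dpl-1 (-3.68) and arf-1.1 (5.63) are uncertain, with 61.5%, 10.9%, 40.2% and 79.7% of exon reads unique, as are those of fat-5 and ergo-1, which another feature overlaps. In all, 1259 genes had a higher and 2242 a lower starvation effect of 17764 tested.

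Fry tests whether a list moves on balance one way and does not compare it with other genes. By fry, 16 of 31 lists differed between the inducers in N2. The camera test called 21 lists with a preset correlation and 0 with an estimated one (smallest adjusted p = 0.169 with an estimated correlation, Benjamini-Hochberg). Antimicrobial and immune genes (median difference 2.95, adjusted p = 0.0031), dauer and stress effector genes (1.69, adjusted p = 0.00242) and intestine genes (1.59, adjusted p = 0.00242) had a higher starvation effect (fry, Benjamini-Hochberg). Oocyte and eggshell genes (-2.74, adjusted p = 0.0193), DNA replication genes (-2.23, adjusted p = 0.0141), chromatin modifiers (-2.04, adjusted p = 0.0136), insulin receptor pathway genes (-2.02, adjusted p = 0.0179), small RNA genes (-1.94, adjusted p = 0.0141) and germline genes (-1.86, adjusted p = 0.0179) had a lower one (fry, Benjamini-Hochberg). Among 13288 genes tested in both N2 experiments, 894 rose after pheromone and fell after starvation, where 231.3 were expected by chance, and 247 fell and then rose, where 129 were expected (Fisher's exact test, two-sided, p = 5.5e-27 for the latter). Only 1 gene rose in both and 5 fell in both. Across these genes, which are not independent replicates, the fold changes had a Pearson r of -0.509 and a Spearman rho of -0.587. The 3501 calls became 0 without the second N2 starvation CON library, 282 without the second pheromone PD library, 715 without the second starvation PD library and 1612 without the first pheromone PD library. Upper-quartile scaling moved the median difference of all genes from 0.255 to 0.761 and gave 2008 higher and 1841 lower. The pheromone side of each difference rests on the lone CON library.

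**Figure D2:**
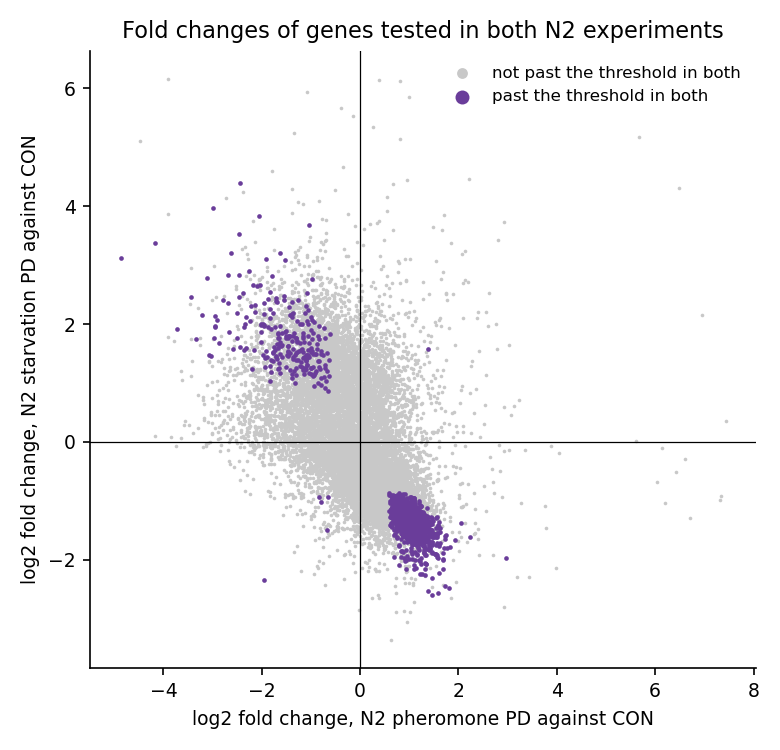
Each point is a gene tested in both N2 experiments, with its log2 fold change (PD over CON) after pheromone on the x axis and after starvation on the y axis, in purple where it passed the threshold in both. Of the purple genes, 894 rose after pheromone and fell after starvation.

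The abundance of csr-1 itself was compared in every experiment. In N2 it averaged 316.8 CPM in the lone pheromone CON library and 619.6 ± 56.41 CPM (SD, n = 2) in PD, a rise of 0.93 ± 0.19 SE on the log2 scale (adjusted p = 0.0391, edgeR quasi-likelihood, Benjamini-Hochberg, higher in 2 of 2 PD libraries). This call was lost in 6 of 14 alternatives, among them the 8-group fit, and the pheromone PD mean was not above the N2 starvation CON mean. In N2 starvation it averaged 678.4 ± 139.2 CPM in CON and 340.5 ± 122.1 CPM in PD (SD, n = 2 each), a log2 value of -1.03 ± 0.41 that missed the threshold (adjusted p = 0.0726, edgeR quasi-likelihood, Benjamini-Hochberg). It was called by the DESeq2 Wald test (adjusted p = 0.0286, Benjamini-Hochberg), by the edgeR exact test (adjusted p = 0.0436, Benjamini-Hochberg) and without the first PD library (-1.508, adjusted p = 0.0425, edgeR quasi-likelihood, Benjamini-Hochberg). Without the second CON library it was -0.703. The difference between the inducers was -2.05 ± 0.64 (adjusted p = 0.0416, edgeR quasi-likelihood, Benjamini-Hochberg). It lost its call in 8 of 20 alternatives, with adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) of 0.0954 and 0.0894 without the first and the second N2 pheromone PD library, 0.136 and 0.116 without the second N2 starvation CON and PD library, and 0.061 and 0.0725 without the first and the second WM193 pheromone PD library. In WM193, csr-1 averaged 905.6 ± 338.8 CPM in pheromone CON, 1270 ± 295.6 in pheromone PD, 841.9 ± 213.3 in starvation CON and 568.9 ± 165.5 in starvation PD (SD, n = 2 each), and neither experiment passed the threshold (log2 0.45 ± 0.31 and -0.37 ± 0.47). Leaving out 1 library moved these values between 0.185 and 0.767, lowest without the second and highest without the first CON library, and between -0.132 and -0.648, without the second and the first PD library. WM193 exceeded N2 in CON adults by 0.87 ± 0.32, which also missed it (adjusted p = 0.0994, edgeR quasi-likelihood, Benjamini-Hochberg). This value was 0.40 without the lone N2 pheromone CON library, and it was called with upper-quartile factors (0.997, adjusted p = 0.0454, edgeR quasi-likelihood, Benjamini-Hochberg) and by the DESeq2 Wald test (0.863, adjusted p = 0.0455, Benjamini-Hochberg). Counts in WM193 mix the transgene with the tm892 transcript. The gene lies on chromosome IV from 7957580 to 7962121 in the coordinates of the deposited tables, whose build is not given in the sources used here.

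**Figure D3:**
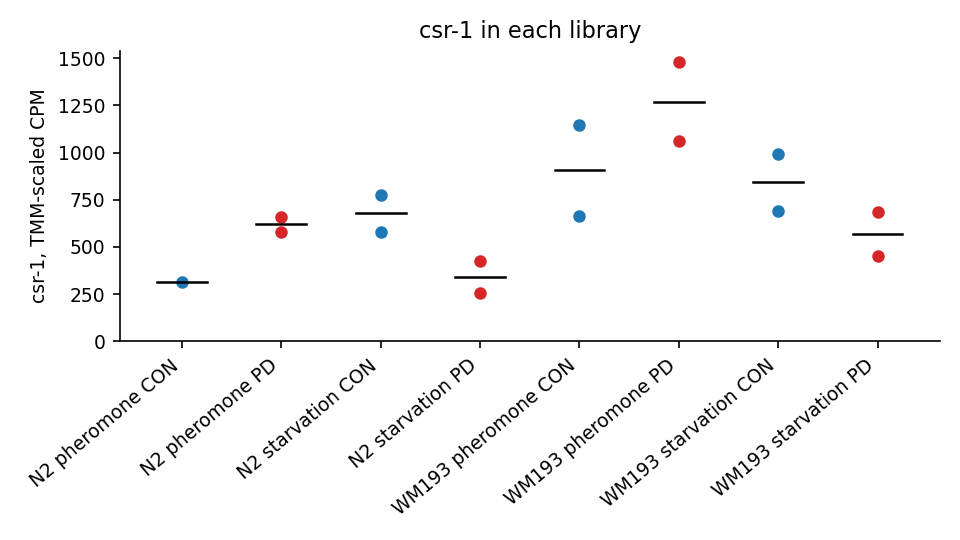
csr-1 abundance in TMM-scaled CPM (y axis) in each library (points, blue CON and red PD) of the 8 groups (x axis), with bars at the group means. The group means run from 316.8 in N2 pheromone CON to 1270 in WM193 pheromone PD.

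In WM193 the pheromone experiment asked whether post-dauer adults of the csr-1 strain differ from their continuous counterparts. Defence and intestine genes had lower values in PD, but no single gene passed the threshold over all genes. Muscle and neuropeptide genes also took a smaller share of exon reads in both PD libraries than in both CON libraries. Of genes named in other comparisons, and so picked after their values were seen, the aspartyl protease gene asp-17 measured 109.8 and 66.08 CPM in CON and 7.163 and 7.972 CPM in PD (log2 -3.57 ± 0.28 SE). The lysozyme gene lys-7 measured 265.2 and 203.7 CPM in CON and 84.46 and 84.7 in PD (-1.51 ± 0.20), spp-2 25.22 and 18.06 against 5.097 and 5.284 (-2.101 ± 0.260), and mtl-1 41.87 and 22.61 against 5.124 and 3.708 (-2.88 ± 0.39). Each of these 4 genes was lower in 2 of 2 PD libraries, at an adjusted p of 0.735 (edgeR quasi-likelihood, Benjamini-Hochberg). Values of cbd-1 (0.18 ± 0.34) and lin-41 (0.26 ± 0.29) were smaller than their SE. Adjusted over the list alone, 6 of 26 intestine genes fell (median -0.52), 4 of 69 antimicrobial and immune genes (median -0.87), 10 of 59 sperm genes outside the msp family (median -0.29, or -0.04 without the second CON library and -0.61 without the first PD library) and 2 dauer and stress effector genes (median -0.45), while over all genes tested the count was 0 in each. By fry's mixed test, which asks whether members change in either direction, 5 lists passed, with an adjusted p of 0.0166 for antimicrobial genes (fry, Benjamini-Hochberg). For a move on balance one way fry called 0 lists, with adjusted p = 0.176 as the smallest (fry, Benjamini-Hochberg). The camera test with a preset correlation gave adjusted p = 6.23e-17 for antimicrobial genes and adjusted p = 0.396 with an estimated correlation (Benjamini-Hochberg). The edgeR quasi-likelihood count was 0 of 15567 genes, with 769 at an unadjusted p under 0.05, against 48 by the DESeq2 Wald test, 39 by the edgeR exact test and 0 by limma-voom, and it was 75 without the first PD library, 3 without the second and 1 without the second CON library. Upper-quartile scaling moved the median of all genes from -0.052 to -0.165, and library totals to -0.141, with 0 calls in both.

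The WM193 starvation experiment asked the same for starvation-induced dauer. Ribosomal protein values were higher in PD and sperm gene values lower, and no single gene passed the threshold. Positive values were found for 78 of 79 ribosomal proteins (median log2 0.93, or 0.25 without the first PD library), and all 25 tested major sperm protein genes were lower adjusted over the list alone, with 0 over all genes (median -3.50). The sperm values followed the first CON library, in which these genes took 0.154% of exon reads against 0.0116% in the next highest starvation or pheromone CON library, and without it the median was -0.51. The sperm-supplied egg activator gene spe-11 had 57.73 CPM in that library and at most 4.62 in any other. Of genes picked after their values were seen, lys-7 had a log2 value of -1.80 ± 0.59 SE, far-3 3.69 ± 1.05, ins-19 1.91 ± 0.67, ins-7 -2.22 ± 0.85 and asp-17 -2.22 ± 0.90, each at an adjusted p of 0.52 (edgeR quasi-likelihood, Benjamini-Hochberg). Every list that camera called with a preset correlation had adjusted p = 0.893 or more with an estimated correlation (Benjamini-Hochberg). Fry called 0 lists, with adjusted p = 0.791 as the smallest for a move on balance (fry, Benjamini-Hochberg), and its mixed test called 0. The edgeR quasi-likelihood count was 0 of 16135 genes, with 1494 at an unadjusted p under 0.05, against 490 by the DESeq2 Wald test (21 higher, 469 lower), 2 by the edgeR exact test and 0 by limma-voom. It was 3065 without the second CON library, 3 without the first CON library and 10 with sequencing lane as a term.

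The inducers were compared within WM193 by the same interaction. Antimicrobial and immune genes had a median difference of 1.24, or 0.67 without the second pheromone CON library and 0.56 without the second starvation PD library, beside a median of 0.041 for all genes that upper-quartile scaling moved to 0.161. No list passed camera with an estimated correlation (adjusted p = 0.663 or more with an estimated correlation, Benjamini-Hochberg), and 0 lists passed fry. For csr-1 the difference was -0.90 ± 0.55 SE. For this interaction the self-test recovered 16% of changes of log2 2 and 64% of those of log2 3. No gene passed by the edgeR quasi-likelihood test (0 calls, 1514 at an unadjusted p under 0.05, 3 calls by the DESeq2 Wald test). The count was 320 without the second WM193 starvation CON library, and 1 without the first or without the first starvation PD library. Across genes tested in both WM193 experiments, the fold changes had a Pearson r of 0.004 and a Spearman rho of 0.108, and genes are not independent replicates.

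Whether the response to dauer history differs between the strains was tested as the WM193 effect minus the N2 effect for each inducer. For starvation, dauer and stress effector genes, C-type lectins and detoxification enzymes had a lower effect in WM193, and DNA replication genes a higher one. The ins-7 difference was -5.90 ± 0.97 SE, with group means of 0.279 CPM in N2 CON, 3.602 in N2 PD, 4.292 in WM193 CON and 0.771 in WM193 PD. The cation ATPase gene catp-3 differed by -3.79 ± 0.64, the transthyretin-like genes ttr-44 and ttr-18 by -3.04 ± 0.54 and -2.99 ± 0.48, the thaumatin-like gene thn-2 by -2.58 ± 0.43 and the lectin genes clec-81 and clec-1 by -2.89 ± 0.46 and -2.24 ± 0.40. For thn-2, both N2 PD libraries (80.92 and 79.97 CPM) exceeded both N2 CON libraries (19.15 and 10.43), and both WM193 PD libraries (39.33 and 44.66) lay under both CON libraries (49.43 and 57.74). Values of nspc-10 (-4.25 ± 0.69) and nspc-14 (-4.08 ± 0.70) are uncertain, as 52% and 51.1% of their exon reads were unique, and those of ttr-44 and clec-81 because another feature overlaps each. Of 17764 genes tested, 39 passed, all with a lower effect in WM193 and each at a rounded adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg). By fry, 11 lists differed: dauer and stress effector genes (median -1.61), C-type lectins (-1.68), detoxification enzymes (-1.84) and intestine genes (-1.09), each at an adjusted p of 0.0069, were lower, and DNA replication genes (1.62) and chromatin modifiers (1.05), each at 0.039, were higher (fry, Benjamini-Hochberg). By camera 0 lists passed at an estimated correlation, where the smallest was adjusted p = 0.26 with an estimated correlation (Benjamini-Hochberg). Adjusted over the list alone, 26 of 26 replication genes and 72 of 181 detoxification enzymes differed in those directions, against 0 over all genes tested. Of all 17764 genes, 6703 had an unadjusted p under 0.05 (edgeR quasi-likelihood), a looser threshold. The 39 calls became 4255 (1517 higher, 2738 lower) without the second WM193 starvation CON library, 2922 (1551 higher, 1371 lower) without the second WM193 starvation PD library, and 0 or 1 without any other single library of a replicated group. The DESeq2 Wald test called 1102 higher and 2722 lower. The single direction of the 39 calls thus depended on the libraries and the test. Upper-quartile scaling gave 266 higher and 1514 lower, moving the median of all genes to -0.379, DESeq2 size factors gave 42 higher and 627 lower, and edgeR quasi-likelihood calls fell to 0 with unique exon reads, a setting added after seeing the data that left 6646 genes at an unadjusted p under 0.05, and at an adjusted p under 0.01.

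For pheromone, the strains were not distinguished gene by gene. The self-test recovered only 6% of changes of log2 2 and 44% of those of log2 3 for this difference, so differences of that size could be missed. Among genes with a mean of at least 5 CPM, 1737 of 2171 that passed in N2 had the same sign in WM193 (80%), whereas for starvation 1526 of 3448 did (44.3%). Over all genes tested in both strains, called or not, the sign agreed in 67.8% of 13440 for pheromone and 41.2% of 14113 for starvation. Across these genes, which are not independent replicates, the strains' fold changes had a Pearson r of 0.414 and a Spearman rho of 0.432 for pheromone, and -0.153 and -0.16 for starvation. With a mean of at least 5 CPM they had 0.433 and 0.363 for pheromone, and -0.076 and -0.042 for starvation. Swapped CON and PD labels in an N2 experiment, weighed further below, stay open and would turn that experiment's signs. Ribosomal proteins had a higher pheromone effect in WM193 for 76 of 79 genes (median 0.73, camera adjusted p = 3.48e-20 with a preset correlation and adjusted p = 0.848 with an estimated correlation, Benjamini-Hochberg). Insulin receptor pathway genes had a median difference of -0.998, beside a median of -0.157 for all genes. The N2 side of both differences rests on the lone CON library. Its median log2 ratio to N2 starvation CON was 0.452 for ribosomal protein genes and -1.03 for insulin receptor pathway genes. For N2 pheromone PD the ratio to N2 starvation CON was 0.083 and -0.21. An unusual lone CON library was therefore not told apart from a strain difference in these lists. By fry 0 lists passed for the strain difference of the pheromone effect. The csr-1 difference was -0.50 ± 0.62 SE, short of the threshold. The edgeR quasi-likelihood test called 0 genes, with 653 at an unadjusted p under 0.05, and the DESeq2 Wald test called 0.

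Continuously developed adults of both strains were compared to describe the strain background. The RNA interference genes sid-1 and rde-11, the P-granule gene deps-1 and a pair of neighbouring F-box genes were lower in WM193, and lys-7, mtl-1 and some lectin and sperm genes were higher. The systemic RNA interference gene sid-1 (chromosome V, 5119970 to 5126916) differed by -3.02 ± 0.32 SE. The P-granule gene deps-1 (chromosome I, 506472 to 509056) differed by -2.78 ± 0.28, and the RNA interference factor gene rde-11 (chromosome IV, 13105323 to 13106926) by -2.64 ± 0.29. The F-box genes fbxa-192 (chromosome V, 17640672 to 17650522) and fbxa-193 (17653482 to 17655281) differed by -3.09 ± 0.29 and -4.10 ± 0.41. Their adjusted p values ran from 0.000333 for fbxa-192 to 0.000933 for rde-11 (edgeR quasi-likelihood, Benjamini-Hochberg). Every one of the 8 WM193 libraries, CON or PD, lay below every one of the 7 N2 libraries for sid-1 (4.101 to 10.21 against 26.89 to 94.13 CPM), deps-1 (13.13 to 44.85 against 83.97 to 368), rde-11 (4.711 to 10.22 against 14.4 to 62.66) and fbxa-192 (1.098 to 2.812 against 5.78 to 17.24). The transgene marker unc-119 was higher in WM193 by 1.75 ± 0.26, with 30.31 to 67.79 CPM in WM193 libraries and 10.05 to 14.16 in N2 libraries. Higher genes included the dehydrogenase gene dhs-26 (6.33 ± 1.09), the kelch-repeat gene kel-10 (5.03 ± 1.06), asp-17 (4.97 ± 0.83), mtl-1 (4.65 ± 0.60), spe-11 (4.62 ± 1.095), the Argonaute gene wago-10 (3.95 ± 0.97), clec-52 (3.54 ± 0.53), lys-7 (3.38 ± 0.43), flp-13 (3.09 ± 0.64), ins-7 (2.85 ± 0.60) and fat-5 (2.69 ± 0.60), with adjusted p from 0.00293 to 0.0464 (edgeR quasi-likelihood, Benjamini-Hochberg). Of these, kel-10 reached 69.95 CPM, spe-11 57.73 CPM and wago-10 24.73 CPM in the first WM193 starvation CON library alone, and no other library exceeded 4.559, 4.62 and 2.639. The calls of spe-11, wago-10, ins-7, fat-5, flp-13 and kel-10 were lost in 15, 14, 11, 11, 9 and 8 of 23 alternatives, and those of the lower genes gsto-1, rpl-22 and rpl-35 in 12, 14 and 12. Lower genes also included the glutathione transferase gene gsto-1 (-1.93 ± 0.44) and the ribosomal protein genes rpl-22 (-1.18 ± 0.28) and rpl-35 (-1.16 ± 0.25). Of these, rpl-22 measured 2307 CPM in the lone N2 pheromone CON library and 758.4 and 756.8 CPM in N2 starvation CON. Values of deps-1, fat-5, gsto-1 and rpl-35 are uncertain because another feature overlaps each.

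In this strain comparison 540 genes were higher and 378 lower in WM193 CON of 17764 tested. C-type lectins were higher in 13 of 181 cases, 28 adjusted over the list alone (median 1.11, fry adjusted p = 0.0325, Benjamini-Hochberg), and dauer and stress effector genes in 7 of 29, 13 adjusted over the list alone (median 0.65, fry adjusted p = 0.0488, Benjamini-Hochberg). No list passed camera with an estimated correlation (adjusted p = 0.645 or more with an estimated correlation, Benjamini-Hochberg), and the second WM193 starvation CON library stood apart in its share of C-type lectin reads, 0.81% against 0.562% or less in the other WM193 CON libraries. Ribosomal proteins were lower in 7 of 79 cases, 59 adjusted over the list alone (median -0.89, or -0.63 without the lone N2 pheromone CON library), with a camera adjusted p of 1.99e-30 at the preset correlation and adjusted p = 0.645 with an estimated correlation (Benjamini-Hochberg). They took 15.45% of exon reads in that lone library, 8.581% and 9.072% in N2 starvation CON and 6.156% to 8.605% in WM193 CON. Sperm genes outside the msp family were higher in 11 of 77 cases, 37 adjusted over the list alone (median 1.96), beside the sperm-rich WM193 starvation CON library. F-box and MATH-BTB genes were lower in 19 of 418 cases and higher in 5, and adjusted over the list alone in 20 and 5, with a positive median (0.05) and mean (0.35) but a negative camera direction. The median gene lay 0.15 higher in WM193, and 0.299 higher with upper-quartile scaling, which gave 640 higher and 205 lower, while DESeq2 size factors gave 478 higher and 210 lower. The 918 calls became 3240 without the second WM193 starvation CON library, 469 without the N2 pheromone CON library, 99 and 77 without the first and second N2 starvation CON library, 108 without the second WM193 pheromone CON library and 126 without the first WM193 starvation CON library. Of the PD libraries, which bear on the spread, leaving out the first or the second gave 208 or 206 for N2 pheromone, 404 or 417 for N2 starvation and 118 or 130 for WM193 pheromone. A fit of the 7 CON libraries alone called 45 genes, and sequencing lane as a term, with the N2 pheromone CON library left out as well, left 65. The call of sid-1, deps-1, rde-11, fbxa-192, fbxa-193 and lys-7 held in each of 23 alternatives.

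**Figure D4:**
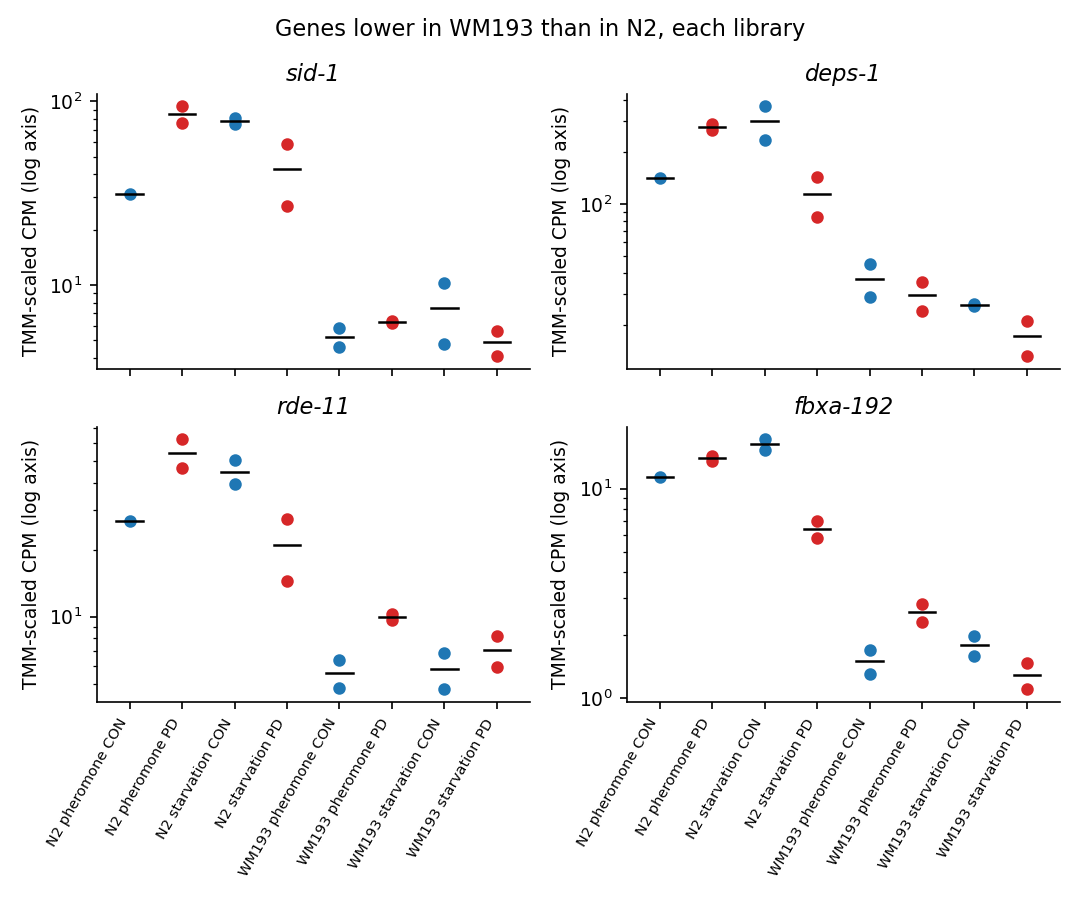
TMM-scaled CPM (y axis, log scale) of sid-1, deps-1, rde-11 and fbxa-192 in each library (points, blue CON and red PD) of the 8 groups (x axis), with bars at the group means. Each WM193 library lies below each N2 library, for sid-1 at 10.21 or less against 26.89 or more.

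Changes shared by all 4 experiments were sought by a PD against CON term with experiment as a factor. A glucuronosyltransferase and a cytochrome P450 gene were among the 6 genes that passed, all higher in PD, of 16490 tested, and 3 of the 6 had no symbol. The glucuronosyltransferase gene ugt-37 rose by 3.39 ± 0.69 SE (adjusted p = 0.00258), the cytochrome P450 gene cyp-13A12 by 3.30 ± 0.54 (adjusted p = 9.84e-06) and the lipid-binding protein gene far-3 by 2.98 ± 0.59 (adjusted p = 0.00175; edgeR quasi-likelihood, Benjamini-Hochberg), and values of ugt-37 and far-3 are uncertain because another feature overlaps each. The median prior degrees of freedom of this fit were infinite. For the median gene the quasi-likelihood spread was thus pooled over genes and not taken from that gene's own 4 experiments. Small adjusted p-values of this fit therefore do not measure agreement between the experiments. In the second N2 starvation PD library cyp-13A12 measured 230.2 CPM against 1.62 in the first, and ugt-37 45.05 against 0.472. In the second N2 pheromone PD library far-3 and cyp-13A12 lay below CON, at 12.17 against 27.03 CPM and 0.523 against 0.769. The calls of ugt-37, far-3 and cyp-13A12 were lost in 7, 7 and 5 of 12 alternatives. All 79 ribosomal proteins had positive values (median 0.24, or 0.06 without the WM193 starvation, 0.12 without the WM193 pheromone and 0.42 without the N2 pheromone experiment, camera adjusted p = 1.34e-08 with a preset correlation and adjusted p = 0.993 with an estimated correlation, Benjamini-Hochberg). With TMM scaling the median of the ribosomal list was negative in both N2 experiments and positive in WM193 starvation. These positive values therefore do not show a rise shared by all 4 experiments. Fry called 0 lists for the shared change. The csr-1 value was 0.04 ± 0.51. The 6 calls became 0 without the N2 starvation experiment, 1 without the first WM193 starvation CON library and 0 with upper-quartile scaling, which left 41 genes at an unadjusted p under 0.05.

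The authors' deposited table for each experiment also held a test of PD against CON. At an adjusted p under 0.05 in the authors' deposited tables, 441 genes were higher and 560 lower in N2 pheromone, 1121 and 551 in N2 starvation, 3 and 87 in WM193 pheromone, and 48 and 224 in WM193 starvation. The edgeR quasi-likelihood test called 791 and 1568 of the genes from the authors' deposited tables in the same direction in N2 pheromone and N2 starvation, and 0 in each WM193 experiment. All genes called in the authors' deposited tables and tested here had the same sign, 1001, 1666, 87 and 272 in that order of experiments.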

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

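The tests of the germline genes against other libraries and within lanes, and of swapped labels, were chosen after those results were seen. The sperm gene tests concern a library picked for its high share of sperm reads, so they followed that result. Their bounds were written before the tests were run.

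Shares of exon reads taken by gene lists set some libraries apart from the other 3 of their strain and history, with both inducers pooled in each group of 4. In the first WM193 starvation CON library, major sperm proteins took 0.154% and other sperm genes 0.242%, where the nearest CON library had 0.0116% and 0.0553%. The second WM193 starvation CON library had 0.81% in C-type lectins and 8.61% in ribosomal proteins, with the nearest at 0.562% and 6.23%. Chemoreceptor genes took 0.0436% in the second WM193 pheromone CON library (nearest 0.0261%), and molting genes 0.0203% in the second WM193 pheromone PD library (nearest 0.0857%). In the second WM193 starvation PD library, fatty acid synthesis genes took 0.634%, fatty acid oxidation genes 0.668% and detoxification enzymes 0.338%, with the nearest at 0.431%, 0.331% and 0.195%. In N2, yolk proteins took 22.2% of the first starvation PD library (nearest 8.29%), and neuronal genes 0.122% of the second (nearest 0.104%). Of 108 such tests 11 gave a separate library, and chance sets apart about 1 in 20 groups, or 5.4 of these.

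The sperm transcripts of the first WM193 starvation CON library were weighed further. Reads shared between paralogs were argued against, since with unique exon reads the median ratio of sperm genes to the highest other library was 7.49. Of the 14 sperm genes tested, 85.7% were highest in this library, with gsp-3 and gsp-4 at 16.8 and 17.1 times the next library and only spe-39 and spe-44 at less than it. This restates the high share and does not tell one source from another, so males or other sperm-making animals in the sample stay open, and the labels name no sex.

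The effects of starvation and of pheromone differed in N2 by the interaction test in 3501 genes, and 16 lists differed by fry. The largest differences among genes with a symbol and a mean of at least 5 CPM were 9.43 for ins-19, 5.78 for spp-2, 5.76 for mtl-1, 5.63 for arf-1.1 and 5.51 for hsp-16.41, and in the other direction -4.25 for lin-41, -3.98 for gla-3, -3.86 for meg-2, -3.86 for puf-3 and -3.68 for dpl-1.

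The opposite germline changes behind this difference were weighed in both N2 experiments. For the fall after starvation, unusual CON libraries were argued against, because the list's median log2 ratio of starvation PD to each of the 3 N2 pheromone libraries was -0.667 at the highest, and lane was argued against by within-lane medians of -0.70 and -1.82. For the rise after pheromone, an unusual lone CON library may account for it, since the pheromone PD libraries exceeded N2 starvation CON by a median of only 0.107, and lane and history cannot be told apart because 0 lanes held both CON and PD libraries. Swapped CON and PD labels in one N2 experiment may account for the opposite changes too, since the lower of the Pearson correlations between N2 and WM193 fold changes, for starvation, was -0.153 across all genes tested in both strains, under the bound of -0.1. Among genes with a mean of at least 5 CPM it was -0.076, between the bounds, so the explanation rests on the choice of genes and stays open. The inducer itself stays open as an untested biological explanation.

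The starvation effect also differed between the strains, in 39 genes by the interaction test and in 11 lists by fry. The lowest values among genes with a symbol and a mean of at least 5 CPM were -4.25 for nspc-10, -4.08 for nspc-14, -3.79 for catp-3, -3.04 for ttr-44 and -2.99 for ttr-18. No explanation was tested for these.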

How the results depend on the processing

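Unique exon reads, lane terms, the fit of the 7 CON libraries alone, the 8-group fit of N2 pheromone with a block or without a library, and leaving out the first WM193 starvation CON library from the shared-change fit were chosen after seeing the data.

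No named gene reversed its direction under any alternative in which either value was called. Of 5214 values of named genes under alternatives, 3731 kept their side of the threshold, 1478 kept the direction but lost the call, 5 gained one and 0 reversed. Apart from csr-1, these genes had been named because they were called. In an experiment, the highest and lowest of them also had all PD libraries on one side of all CON libraries. The 0 reversals are therefore partly set by the naming rule and do not measure robustness. Counts of calls varied as follows, and the cause was not tested except where fewer libraries or a stricter threshold bring it about.

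In N2 pheromone the 2309 calls became 0 in the 8-group fit, 0 in that fit with the library number as a block, 0 to 0 in it without either PD library, 1441 with upper-quartile factors, 3543 with no filter on low counts and 1272 at a change of at least 2-fold. In N2 starvation the 4372 calls became 2819 with library totals only, and 0 to 4523 without 1 library, lowest without the second CON library.

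In WM193 pheromone the 0 calls became 48 by the DESeq2 Wald test, 39 by the edgeR exact test, 6 with the replicate block, and 0 to 75 without 1 library. In WM193 starvation the 0 calls became 490 by the DESeq2 Wald test, 2 by the edgeR exact test, 10 with sequencing lane as a term, and 0 to 3065 without 1 library. The 0 calls of the inducer difference in WM193 became 3 by the DESeq2 Wald test and 0 to 320 without 1 library. The pheromone effect gave 0 calls between strains in every alternative run. In the self-test of its main fit 6% of changes of log2 2 were recovered, so these counts do not show that the strains respond alike.

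The 6 calls shared by the 4 experiments became 0 with upper-quartile factors, 0 as the mean of 4 contrasts over libraries, 0 as that mean with the replicate block, 1 without the first WM193 starvation CON library, and 0 to 5 without 1 experiment. The inducer difference in N2, 3501 calls, became 1549 with the replicate block and 0 to 4006 without 1 library.

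The 39 calls of the strain difference of the starvation effect became 669 with DESeq2 size factors, 1780 with upper-quartile factors, 1060 with no filter on low counts, 3824 by the DESeq2 Wald test, 0 with the replicate block, 0 with sequencing lane as a term and no N2 pheromone CON library, 0 with unique exon reads, and 0 to 4255 without 1 library. The 918 calls between WM193 and N2 in CON adults became 2574 by the DESeq2 Wald test, 608 with no filter on low counts, 39 with the replicate block, 65 with sequencing lane as a term and no N2 pheromone CON library (469 without that library alone), 45 in the 7 CON libraries alone, and 77 to 3240 without 1 library.

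At an adjusted p under 0.01 the counts were 0 in N2 pheromone, 226 in N2 starvation, 4 for the inducer difference in N2, 0 for the strain difference of the starvation effect and 69 between strains in CON adults. At that threshold in both N2 experiments, the counts of genes higher in both, lower in both, higher then lower, and lower then higher were 0, 0, 0 and 0. With an estimated correlation, camera called 0 lists in each of the 10 comparisons, where the preset correlation had called 11 to 23.

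The replicate block used the order of the libraries within a group. The labels do not say that libraries of the same order are pairs, so this block was only an alternative. Across genes, the difference between the libraries of CON correlated with that of PD at r = -0.256 in N2 starvation, -0.8 in WM193 pheromone and -0.18 in WM193 starvation. Depth limits the lone N2 pheromone CON library most, with 8424878 exon reads.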

Other observations

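The test of the 4 strain genes against germline RNA and the fit of the 7 CON libraries alone, on which the strain splits rest, were chosen after the results were seen. The tests of lane and deletion concern genes picked by their values in the strain comparison, so they followed that result. Their bounds were written before the tests were run. The splits of the 4 experiments were not chosen after the results were seen.

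Further genes changed in N2. After starvation the MATH-domain gene math-38 rose by 4.27 and the F-box gene fbxa-164 by 4.72. The molting regulator nhr-23 rose by 1.33 after pheromone and fell by 1.68 after starvation, and the proteasome gene rpn-1 rose by 1.28 and fell by 1.61. The lipase genes lipl-4 and lipl-3 rose by 3.6 and 2.70 after starvation, and the steroid hormone genes daf-36 and nhr-8 by 1.47 and 1.19, values that are uncertain because another feature overlaps each. These starvation calls are among those lost without the second N2 starvation CON library, which left 0. The pheromone rises of nhr-23 and rpn-1 rest on the lone CON library, at 31.98 and 197.7 CPM. Pheromone PD and N2 starvation CON had at least 77.02 and 483.6 CPM. Both pheromone calls were lost in the 8-group fit, which called 0 genes.

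The lower values of sid-1, deps-1, rde-11 and fbxa-192 in WM193 were weighed against other causes. Less germline RNA was argued against, since the germline and meiosis list had a median log2 value of -0.05 (SD 0.593 over its members; 0.078 with upper-quartile scaling). Lane was argued against, as within lane 7 the highest WM193 library was at most 0.71 of the lowest N2 library for each of the 4 genes. A full deletion was argued against by at least 42 unique exon reads of each gene in every WM193 library, and a partial deletion was not tested. The csr-1 genotype, the transgene and other differences between the strains remain as untested biological explanations.

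In a fit of the 7 CON libraries, the real split into 3 N2 and 4 WM193 libraries called 45 genes, and among all 35 splits of the libraries only it, 1 split, called as many, with 0 calls as the highest of the others. These libraries come from 4 samples, and libraries of 1 sample may not be independent, while splits of the 4 samples, 3 in number, are too few for a share under 0.05. For the change shared by the 4 experiments the real split called 6 genes, 8 of 32 splits of the 8 groups called as many, and the highest of the others called 1683, so chance could not be excluded. That highest split codes the N2 experiments in opposite directions, which points to a structure of the samples. Splits that separate the members of only 2 experiments come in pairs with the same fit, so the 32 splits are not all distinct. Those that separate the members of all 4 experiments are too few for a share under 0.05.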
